A study of Ovis aries with 20 samples.

How the data were processed

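Per the labels, total RNA came from frozen tracheal tissue of sheep, called epithelial, homogenised in an acid phenol reagent, from normal and CF animals at days 65, 80, 100, 120 and 147. Per the submitters' processing notes, reads were aligned with STAR 2.6 and counted with featureCounts 1.6.3 of the Subread package. The deposited values are raw counts per gene, whole numbers with a different total in each sample, in a table of WT and a table of CF samples with the same genes in the same order. Per the file headers the tables also hold positions and summed exon lengths of the genes. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. No reference genome was used here, so sequence around the CFTR gene was not analysed here. Of 24478 genes, 8432 carry an identifier in place of a symbol, and 573 of these were given a symbol from the RefSeq gene table of assembly ARS-UI_Ramb_v3.0, used for names only.

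Each sample was placed in its group by its title. The replicates of every group differed by more than counting noise, with a chi-square per gene from 39.3 to 1744, so none was a copy of another. That does not show separate animals, and those of a group that share an identifier may be 1 animal. WT day 65 replicate 2 and CF day 100 replicate 2 also share one, but by their titles they differ in genotype and age. If the titles hold, they cannot be 1 animal, and an identifier need not stand for an animal. Each replicate was kept as a sample, and a fit with the WT day 100 pair and the CF day 147 pair each summed is among the alternatives. This is the fit meant where samples of a shared identifier are summed, and the pair across genotypes was summed in none. Total counts ran from 42372433 to 87651829 per sample. A gene at 0 in a group is given against a floor of 3 counts over the group, which covers counting error only. Of the values from 1 to 20 in a library, 70.7% to 85.3% were even, against 50.1% to 58.3% of those of at least 1000, as would follow from both reads of a pair being counted. Whether reads were paired is not given in the sources used here. If so, there are fewer independent molecules than counts, and a floor of 6 counts is the matching one, at which IGF2BP1 is at least 429.6-fold lower in WT at birth than at day 65 and at least 12.5-fold higher in CF than in WT at birth, RNASE12 at least 21.2-fold higher in CF at day 65 and FOXI1 at least 22.4-fold lower in CF at day 80.

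Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 10 groups (20097 genes), library sizes were scaled by TMM, and a quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) had 1 coefficient per group of genotype and age, so that all 20 samples share the estimate of the spread. Adjusted p are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. SE are the log2 fold change divided by the root of the quasi-likelihood F. CPM, the depth-scaled counts, use the TMM library sizes. The contrasts were CF against WT over the mean of the ages and at each age, day 147 against day 65 in WT and in CF, the difference of these, and an F test that the genotype difference is the same at all ages.

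Before the data were examined, 40 gene lists with 1792 members were fixed, covering cell types of the airway, tissues next to it, signalling pathways and cell states, and a list of liver genes was added afterwards. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg within a comparison. An estimated correlation and fry were alternatives. No list test was run with samples of a shared identifier summed, so list p-values take them as separate samples. A list score is the mean over members of the log2 CPM minus the gene's mean over all libraries.

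The genes named in the text follow a rule also fixed before the data were examined. It takes 21 key genes, of which 20 were tested, and the 10 genes with the largest fold change per direction for the mean of the ages (same sign at all ages) and for each development. It takes the 5 largest per direction at each age and for the difference of developments, with no overlap between the groups, and up to 4 members of each list that passed. Genes of the largest folds needed a symbol and a mean log2 CPM of at least 1. H19 was matched to no gene and SFTPC was near 0 in all groups, and neither is given. A few genes that the rule takes are not reported here.

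On simulated counts drawn from the real gene means, library sizes and fitted dispersions, the edgeR step for the mean of the ages called 41.8% of genes changed 2-fold, 91.0% changed 4-fold and 95.5% changed 16-fold among 19768 genes, with 6 unchanged genes called. For a single age, simulated at day 100, it called 0%, 26.9% and 78.8%. For WT development it called 0%, 41.8% and 77.3%. The changed genes were drawn from those with a mean of at least 2 CPM. The simulated libraries held no other tissue, length slope or shared animals, so these figures do not cover errors from such sources. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library size alone, no filter, a stricter filter, a replicate block, summing of samples with a shared identifier, a 2-fold minimum, 1 surrogate variable (sva 3.50.0), fits of 4 samples, a linear trend on day, and leaving out each age or each library.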

Results

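RNA sequencing counts were given for tracheal tissue, labelled epithelial, of sheep at 5 ages, days 65, 80, 100, 120 and 147, the last being birth. At each age the samples came from normal (WT) animals and from animals with cystic fibrosis (CF), the disease caused by loss of CFTR, a chloride and bicarbonate channel of epithelia. Each of the 10 groups held 2 samples, 20 in all. The total count per sample ran from 42372433 in WT day 65 replicate 2 to 87651829 in WT day 100 replicate 2. The series is about early deficits in the development of CF airways, so CF was compared with WT over all ages and at each age, and birth with day 65 within each genotype. Low counts were mostly even: between 70.7% and 85.3% of the values from 1 to 20 in a library were. The sample identifiers were shared by both WT day 100 replicates and by both CF day 147 replicates. Another identifier stood on WT day 65 replicate 2 and on CF day 100 replicate 2, which cannot be 1 animal if their titles hold. The p-values here measure the spread between these samples, which may be technical.

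Some libraries held genes of other tissues, which move with the groups they belong to. TG, encoding thyroglobulin, the precursor of thyroid hormone, took 11% of the counts of WT day 80 replicate 2, and SLC5A5, the iodide importer of the thyroid, stood at 1636 CPM there against 142 in the other WT day 80 library. CF day 65 replicate 2 held the plasma protein genes AHSG, ALB and SERPINA1 at 5346, 4683 and 3568 CPM, against 5.15, 0.695 and 0.851 in its partner. In CF day 80 replicate 1 all 56 skeletal muscle markers tested were over 2-fold above the other CF day 80 library, ACTA1 among them at 5766 against 0.857 CPM. WT day 65 replicate 2 held thymus genes such as PRSS16, at 125 against 0 CPM, and 51 of 56 muscle markers were over 2-fold above its partner. The slope of log2 CPM, as a deviation from the gene's mean, on log2 gene length lay under -0.2 in 4 WT and 1 CF library, and the list of ribosomal protein genes, which are short, moves with it.

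**Figure D1:**
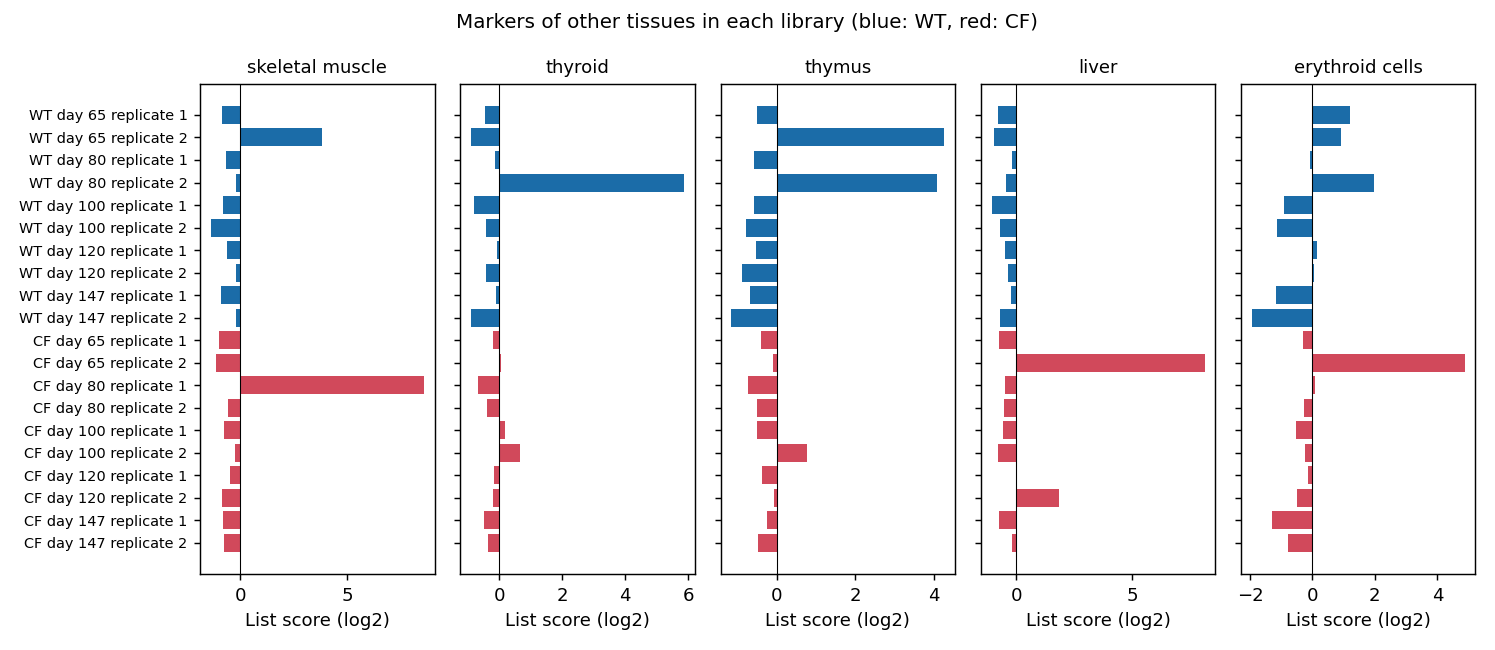
List scores of skeletal muscle, thyroid, thymus, liver and erythroid markers (x axis, mean log2 deviation from the average library) in each of the 20 libraries (bars, blue for WT and red for CF). The bars reach 8.58 for muscle in CF day 80 replicate 1, 5.87 for thyroid in WT day 80 replicate 2 and 8.11 for liver in CF day 65 replicate 2.

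CFTR itself was transcribed in every library of both genotypes. Its level was 37.8 and 21.8 CPM in WT and 16.5 and 11.7 CPM in CF at day 65, and 14.7 and 10.2 CPM in WT and 4.30 and 8.36 CPM in CF at day 80. It was 25.4 and 31.0 CPM in WT and 19.9 and 17.4 CPM in CF at day 100, 35.1 and 16.5 CPM in WT and 14.5 and 30.8 CPM in CF at day 120, and 27.6 and 18.8 CPM in WT and 37.1 and 26.0 CPM in CF at day 147. Over the ages this made 23.9 ± 9.08 CPM in WT and 18.7 ± 10.1 CPM in CF (SD, n = 10 each), from 186 to 2984 counts per library. The log2 fold change over the mean of the ages was -0.48 ± 0.21 (SE) and did not pass (adjusted p = 0.421, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The gene lies on chromosome 4 from 50644000 to 50864925 in the coordinates of the count tables, whose genome build is not given in the sources used here. A count over the whole gene does not show a small insertion or deletion, so these levels do not check the genotype labels.

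**Figure D2:**
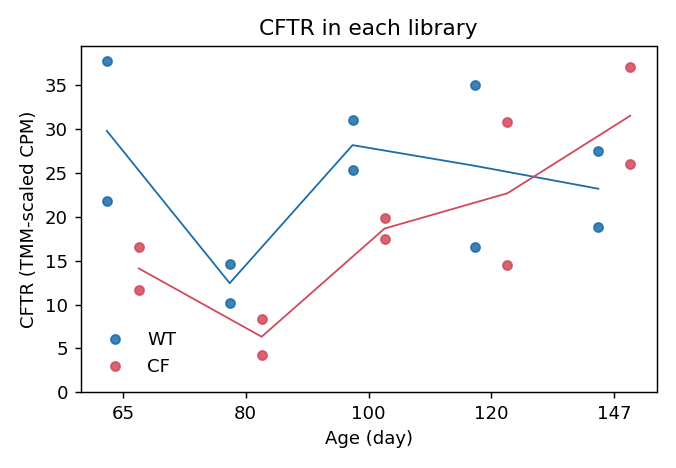
CFTR level (y axis, TMM-scaled CPM) in each library against age in days (x axis), blue points for WT and red for CF, with lines through the group means. The WT libraries lie between 10.2 and 37.8 CPM and the CF libraries between 4.30 and 37.1 CPM.

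Over the mean of the ages, CF tracheas had more RNA of genes induced by low oxygen than WT tracheas, and less of SCNN1B, FCGBP and GSR. SCNN1B, the beta subunit of the epithelial sodium channel ENaC, averaged 4.94 ± 1.76 CPM in CF against 41.5 ± 72.4 CPM in WT (SD, n = 10 each), a log2 fold change of -2.13 ± 0.43 (SE). Without WT day 80 replicate 2 it was at -1.25 and passed, but it did not pass in 17 of 20 fits with 1 library left out. FCGBP, a mucus protein, was at -1.75 ± 0.28 log2, GSR, which regenerates reduced glutathione, at -1.58 ± 0.27, and SLC39A4, a zinc importer, at -1.91 ± 0.37. LPO, the lactoperoxidase of airway secretions, was higher in CF by 1.86 ± 0.33, VIL1, an actin bundler of microvilli, by 1.80 ± 0.27, and ACHE, which breaks down acetylcholine, by 2.20 ± 0.36. In all, 154 of 20097 genes passed, 92 higher and 62 lower in CF.

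Among genes with the same sign at every age, the other largest increases in CF were SLC25A47 (2.55 log2), MESP2 (2.01), a somite transcription factor, PRND (1.93), MPV17L (1.6), MROH6 (1.46), MS4A8 (1.36) and KIAA1024L (1.33). The other largest decreases were ADGRG7 (-1.62 log2), ADAM32 (-1.62), PTGFR (-1.47), the receptor of prostaglandin F, TRIM7 (-1.43), RBM46 (-1.40) and RAB6B (-1.28). Their adjusted p ran from 0.00375 to 0.0440 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of 28 named genes called here, 19 lost the call without 1 library or another, 18 of them without CF day 147 replicate 2. Over all 154 genes, leaving out 1 library moved this count by over 1.5 times in 18 of 20 fits, from 51 without CF day 147 replicate 2 to 319 without WT day 80 replicate 1. The count fell to 51 genes without day 100 and to 49 without the 4 libraries holding other tissue. With the WT day 100 pair and the CF day 147 pair each summed, few genes passed. Fewer samples alone need not account for this, as more genes passed without the 5 libraries of low length slope. The calls thus lean on taking each pair as separate samples. With the pairs summed 154 of the 154 genes kept their direction, with a median ratio of the log2 fold changes of 0.993. Summing leaves the group means nearly as they were, so this does not show that the folds hold in separate animals. For the mean larger counts of called genes were 827 (466 higher, 361 lower) by DESeq2, 888 (607 higher, 281 lower) with 1 surrogate variable, 790 (510 higher, 280 lower) with the length slope as a covariate and 387 (231 higher, 156 lower) without the 5 libraries of low length slope. For the mean smaller counts of called genes were 99 (61 higher, 38 lower) without day 80, 90 (58 higher, 32 lower) without day 147, 49 (26 higher, 23 lower) with the WT day 100 pair summed and 52 (32 higher, 20 lower) with the CF day 147 pair summed. SLC25A47 (3.26) moved by over 1.5-fold to this log2 value without WT day 100 replicate 2.

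Of the hypoxia list, genes induced by low oxygen, 5 of 35 members were higher over all genes and 16 adjusted over the list alone (camera adjusted p = 7.88e-13; adjusted p = 0.000882 with an estimated correlation). EGLN3, an oxygen sensor, rose by 0.94 ± 0.12 log2, SLC2A3, a glucose transporter, by 1.19 ± 0.20, PDK1, which holds pyruvate back from mitochondria, by 0.62 ± 0.11, and PGK1, of glycolysis, by 0.56 ± 0.11. Their adjusted p ran from 0.00592 to 0.0308 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). EGLN3 was not higher at every age: its difference ran from -1.21 log2 at day 100 to 3.47 at birth, where both CF libraries share an identifier. The hypoxia list was the 1 list of 15 past the camera threshold here that also passed with an estimated correlation.

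Stromal lists lay higher in CF in the camera test over the mean of the ages, but fibroblast scores were not higher at every age. For fibroblasts and matrix, 2 of 52 members were higher over all genes and 8 adjusted over the list alone (camera adjusted p = 4.63e-11; adjusted p = 0.266 with an estimated correlation). SFRP2, a secreted Wnt modulator of stroma, rose by 1.24 ± 0.15 log2 and LOXL2, a collagen crosslinker, by 0.52 ± 0.10 (adjusted p = 0.00488 and 0.0380, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). For endothelium, 0 of 39 members were higher over all genes and 0 adjusted over the list alone (camera adjusted p = 7.08e-06; adjusted p = 0.544 with an estimated correlation). The Hedgehog list had 0 of 22 members higher over all genes and 6 adjusted over the list alone (camera adjusted p = 8.38e-05; adjusted p = 0.436 with an estimated correlation). These included GAS1 at 0.90 log2. The WT day 100 libraries, with fibroblast scores of -1.47 and -1.76, were the lowest of the 20 for that list. Fibroblast scores were higher in CF at days 80, 100 and 120 but lower at day 65 and at birth. At day 65 they were 0.25 and 0.52 in CF against 0.71 and 0.87 in WT. At birth they were -0.67 and -0.89 in CF against -0.04 and -0.51 in WT. The lists were not tested over the mean without day 100.

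For each further list past the camera threshold, the adjusted p is given first, then the adjusted p with an estimated correlation. Higher in CF were nerve and Schwann cells (0.0217, 0.305), Wnt signalling (0.00834, 0.436) and FGF and BMP signalling (0.00395, 0.183). Lower in CF were epithelium (0.00129, 0.761), ionocytes (0.00274, 0.182), lymphocytes (0.0114, 0.761), thymus (0.00468, 0.761), cell cycle (0.00834, 0.761), oxidative phosphorylation (8.38e-05, 0.761), unfolded protein response (0.00274, 0.436) and ribosomal proteins (0.00395, 0.806). Fewer lists were lower in CF without the 4 libraries holding other tissue. The epithelium score was -1.62 in CF day 80 replicate 1, the library high in muscle, against -0.10 in its partner. CREB3L4, a transcription factor of the secretory pathway, fell by 1.00 log2 (adjusted p = 0.0428, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). FOXI1, the master transcription factor of ionocytes, did not pass (adjusted p = 0.0809, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It had no counts in CF at day 80, and with that age set to its bound against the floor its mean was -1.41 log2, with values of -0.09 at day 65, -0.28 at day 100, -2.21 at day 120 and 1.03 at birth, where it was at 1.52 CPM in CF and 0.743 in WT. Lymphocyte and thymus genes were high in WT day 65 replicate 2 and WT day 80 replicate 2, with thymus scores of 4.28 and 4.09. Liver genes, a list added after the data were seen, were higher in CF (camera 0.000451, 0.750), with scores of 8.11 in CF day 65 replicate 2 and 1.85 in CF day 120 replicate 2, the others at -0.01 or below, and 1 of 28 passed, C3 at 1.17 log2. The ribosomal list turned to higher in CF with the length slope as a covariate (camera adjusted p = 0.518). Oxidative phosphorylation scores moved with the length slope too. They ran from 0.54 to 0.96 in the 5 libraries of low length slope, of which 4 are WT. In WT day 65 replicate 1, the library of highest slope, the score was -0.89. A lower level of this list in CF thus cannot be told apart from that library property.

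**Figure D3:**
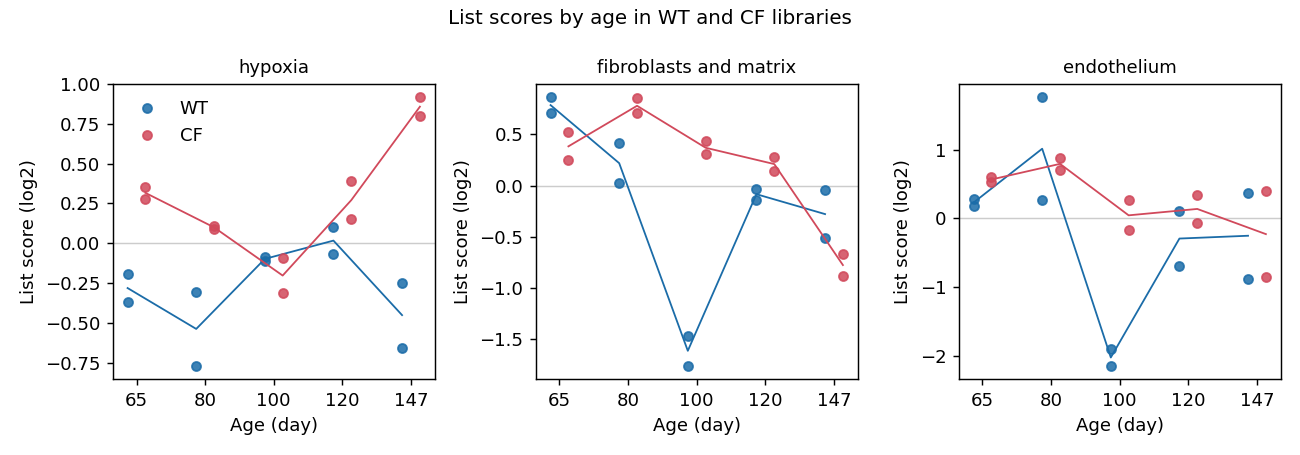
Scores of the hypoxia, fibroblast and endothelium lists (y axis, mean log2 deviation from the average library) against age in days (x axis), blue points for WT and red for CF libraries, lines through group means. At day 147 the CF libraries have hypoxia scores of 0.80 and 0.92 and the WT libraries -0.25 and -0.65.

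At day 65 CF tracheas had higher levels of genes induced by low oxygen and far less ADGRG7, an orphan adhesion receptor. ADGRG7 stood at 0.751 ± 0.0819 CPM in CF against 22.1 ± 5.60 CPM in WT (SD, n = 2 each), a log2 fold change of -4.87 ± 0.58 (SE). RNASE12, of the ribonuclease A family, was at 0 counts in WT and at 0.985 ± 0.573 CPM in CF, at least 42.3-fold higher against a floor of 3 counts over the group and at least 16.4-fold without WT day 65 replicate 1. It was chosen for naming after its values were seen, being below the level the rule asks for. These were the 2 genes called (adjusted p = 0.0199 each, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with 682 at an unadjusted p under 0.05, 150 called by DESeq2 and 0 by limma-voom. Of them 1 passed with library size alone, and leaving out 1 library moved this count by over 1.5 times in 13 of 20 fits, from 0 without WT day 65 replicate 1 to 46 without CF day 65 replicate 1. For day 65 a larger count of called genes was 6 (2 higher, 4 lower) with the length slope as a covariate. For day 65 smaller counts of called genes were 0 (568 at an unadjusted p under 0.05) with both pairs of a shared identifier summed, 0 (350 unadjusted) without the 4 libraries holding other tissue and 0 (607 unadjusted) with the CF day 147 pair summed. Of the hypoxia list, 0 of 35 members were higher over all genes and 7 adjusted over the list alone (camera adjusted p = 2.10e-12; adjusted p = 0.00102 with an estimated correlation). EGLN3 was at 1.27 ± 0.28 log2 and PGK1 at 0.87 ± 0.24.

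Multiciliated cell markers had a median log2 fold change of 0.41 at day 65, with 0 of 120 members higher over all genes and 0 adjusted over the list alone (camera adjusted p = 1.55e-06; adjusted p = 0.794 with an estimated correlation). Fibroblast markers had a median of -0.44, with 0 of 52 members lower over all genes and 0 adjusted over the list alone (camera adjusted p = 6.33e-09; adjusted p = 0.648 with an estimated correlation). In all 13 of 40 lists passed camera at day 65, 8 higher and 5 lower in CF, and 1 passed with an estimated correlation. Fewer passed camera without the 4 libraries holding other tissue. Lists of the tissues seen in single libraries were among those past camera. Lymphocytes (-2.55), thymus (-4.08) and skeletal muscle (-4.40, or -3.82 with members at 0 in a group set to their bound) had negative medians, with WT day 65 replicate 2 high in all, and erythroid cells a median of 2.92, with CF day 65 replicate 2 high. Their camera adjusted p were 7.17e-11, 2.60e-07, 4.37e-10 and 0.000390, and with an estimated correlation the adjusted p were 0.648, 0.648, 0.794 and 0.794.

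At day 80 no gene passed, and 23 of 40 lists passed camera, 9 higher and 14 lower in CF. Of these 1 passed with an estimated correlation, that of hypoxia. Among hypoxia genes, 0 of 35 members were higher over all genes and 0 adjusted over the list alone (camera adjusted p = 5.10e-07; adjusted p = 0.0148 with an estimated correlation). BNIP3, a mitophagy receptor, was at 1.61 log2. Skeletal muscle markers, high in CF day 80 replicate 1, had 0 of 56 members higher over all genes and 43 adjusted over the list alone (camera adjusted p = 4.39e-19; adjusted p = 0.400 with an estimated correlation). Thyroid markers, high in WT day 80 replicate 2, had 0 of 16 members lower over all genes and 12 adjusted over the list alone (camera adjusted p = 8.24e-09; adjusted p = 0.231 with an estimated correlation). Epithelial markers had a median of -0.67 log2, EPCAM among them at -1.22, with 0 of 33 members lower over all genes and 0 adjusted over the list alone (camera adjusted p = 5.76e-07; adjusted p = 0.437 with an estimated correlation). The epithelium score was -1.62 in CF day 80 replicate 1, the library high in muscle, against -0.10 in its partner, and EPCAM stood at 58.3 against 136 CPM. Further lists past camera were, higher in CF, smooth muscle, fibroblasts and matrix, nerve and Schwann cells, Wnt signalling, Hedgehog signalling, FGF and BMP signalling and imprinted genes and, lower in CF, multiciliated cells, ionocytes, interferon response, lymphocytes, antigen presentation, erythroid cells, lung alveoli, thymus, cell cycle, unfolded protein response, cholesterol synthesis and autophagy and lysosome. Their camera adjusted p ran from 1.34e-08 to 0.0487, and with an estimated correlation the adjusted p ran from 0.211 to 0.826. Without the 4 libraries holding other tissue 8 lists passed, 2 higher and 6 lower. FOXI1 was at 0 counts in both CF libraries, at least 44.8-fold lower than in WT against a floor of 3 counts over the group and at least 19.5-fold without WT day 80 replicate 2, and did not pass (adjusted p = 0.278, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). By edgeR 0 genes passed, 1924 had an unadjusted p under 0.05, DESeq2 called 693 and limma-voom 0. WT day 80 replicate 1 is among the 5 libraries of low length slope. Fits without it keep of WT day 80 only replicate 2, the library high in thyroid and thymus genes. A fit without CF day 80 replicate 2 keeps of CF day 80 only the library high in muscle. Counts from such fits may reflect those tissues. For day 80 larger counts of called genes were 67 (45 higher, 22 lower) with the length slope as a covariate and 1772 (780 higher, 992 lower) without the 5 libraries of low length slope. Leaving out 1 library, edgeR called 352 without WT day 80 replicate 1, 1 without WT day 80 replicate 2 and 316 without CF day 80 replicate 2.

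At day 100, 294 genes passed, 282 higher and 12 lower in CF, and 25 of those higher were members of the fibroblast and matrix list. COL6A6, a collagen VI chain, stood at 54.0 ± 12.3 CPM in CF against 0.428 ± 0.0564 in WT (SD, n = 2 each), a log2 fold change of 6.97 ± 1.43 (SE). IL1RL2, an interleukin receptor, had 2 counts in WT and 866 in CF, a ratio of 461 with a 95% counting interval from 127 to 3812, or from 82.3 to 18249 if each pair of counts is 1 molecule. The ratio was 207 (56.5 to 1721) without CF day 100 replicate 1, 722 (199 to 5973) without CF day 100 replicate 2 and 285 (78.7 to 2357) without WT day 100 replicate 1, and it was at least 118-fold higher without WT day 100 replicate 2, none passing. TMEM132E (6.18 ± 1.10), RNASE9 (5.74 ± 1.02) and GABRA3 (4.78 ± 0.66) had the other largest increases, with all WT counts of TMEM132E and RNASE9 in WT day 100 replicate 2. PIGR, which carries IgA across the epithelium, stood at 34.4 ± 16.6 against 355 ± 163 CPM, and FCGBP at 97.1 ± 8.07 against 948 ± 313 CPM. The largest decreases were TRIM7 (-3.40 ± 0.53), PIGR (-3.37 ± 0.59), FCGBP (-3.29 ± 0.68), SFTA2 (-2.69 ± 0.55) and NCF4 (-2.50 ± 0.56). Their adjusted p ran from 0.00505 to 0.0474 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). PIGR (-3.97, not passing) moved by over 1.5-fold to this log2 value without CF day 100 replicate 1. RNASE9 (4.75, not passing) and TMEM132E (5.2, not passing) moved by over 1.5-fold to these log2 values without WT day 100 replicate 1. Against the floor RNASE9 was at least 156-fold higher and TMEM132E at least 147-fold higher without WT day 100 replicate 2, neither passing. Of 19 named genes called here, 19 lost the call without 1 library or another, 19 of them without WT day 100 replicate 2.

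Fibroblast and matrix genes were higher in CF at day 100. Of that list 25 of 52 members were higher over all genes and 42 adjusted over the list alone (camera adjusted p = 2.59e-34; adjusted p = 0.0370 with an estimated correlation). COL1A1, a chain of type I collagen, rose by 4.22 ± 0.54 log2, SFRP2 by 2.98 ± 0.35, COL6A1 by 2.6 ± 0.30 and COL14A1 by 2.51 ± 0.30. Of the endothelial list 3 of 39 members were higher over all genes and 29 adjusted over the list alone (camera adjusted p = 4.56e-15; adjusted p = 0.221 with an estimated correlation). These included CD34 (2.47) and LYVE1 (2.36), a lymphatic and macrophage gene. Of the Hedgehog list 4 of 22 members were higher over all genes and 12 adjusted over the list alone (camera adjusted p = 8.13e-08; adjusted p = 0.221 with an estimated correlation), with GAS1 (3.24) and GLI2 (1.65). Of the cartilage list 3 of 42 members were higher over all genes and 7 adjusted over the list alone (camera adjusted p = 0.000393; adjusted p = 0.350 with an estimated correlation), with CILP (3.37). Of the nerve and Schwann cell list 3 of 38 members were higher over all genes and 7 adjusted over the list alone (camera adjusted p = 0.0169; adjusted p = 0.221 with an estimated correlation). CILP (4.68) and LYVE1 (1.77, not passing) moved by over 1.5-fold to these log2 values without WT day 100 replicate 1. CILP (2.59, not passing) and LYVE1 (3.03, not passing) moved by over 1.5-fold to these log2 values without WT day 100 replicate 2.

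Epithelial markers had a median of -0.69 log2 at day 100 with 0 of 33 members lower over all genes and 0 adjusted over the list alone (camera adjusted p = 7.57e-05; adjusted p = 0.512 with an estimated correlation). Of the secretory and goblet list 2 of 38 members were lower over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0362; adjusted p = 0.350 with an estimated correlation). The hypoxia list, higher in CF by camera in the mean and at days 65, 80, 120 and 147, had a median of -0.10 here, with 0 of 35 members lower over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0294; adjusted p = 0.221 with an estimated correlation). The endothelium scores of both WT day 100 libraries, -1.90 and -2.14, were the lowest of all libraries. The median of all genes at day 100 was 0.12 log2, and 0.32 with library size alone. The lists at day 100 were not tested with the WT libraries summed, so their p-values take these as separate samples. Summing leaves the mean of the pair nearly as it was, so it can lower the number of calls but hardly turn a direction. With both WT libraries, which share an identifier, summed into 1 sample and no others, 0 genes passed by edgeR, with 1366 at an unadjusted p under 0.05, and 294 of the 294 kept their direction, with a median ratio of the log2 fold changes of 0.968. For day 100 larger counts of called genes were 1210 (986 higher, 224 lower) by DESeq2, 5759 (2761 higher, 2998 lower) in the fit of the 4 samples alone, 750 (673 higher, 77 lower) with the length slope as a covariate and 550 (478 higher, 72 lower) without the 5 libraries of low length slope. For day 100 a smaller count of called genes was 0 (1226 at an unadjusted p under 0.05) with both pairs of a shared identifier summed. Leaving out 1 library gave 482 without WT day 80 replicate 2, 39 without WT day 100 replicate 1, 0 without WT day 100 replicate 2, 92 without CF day 100 replicate 1, 60 without CF day 100 replicate 2, 171 without CF day 120 replicate 1 and 150 without CF day 147 replicate 2.

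At day 120 no gene passed, and 8 lists passed camera, 4 higher and 4 lower in CF, of which 0 passed with an estimated correlation. By edgeR 0 genes passed, 279 had an unadjusted p under 0.05, DESeq2 called 17 and limma-voom 0. For day 120 a larger count of called genes was 1 without the 5 libraries of low length slope. Neuroendocrine markers had a median of -0.73 log2, INSM1 at -1.10 among them, with 0 of 29 members lower over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000527; adjusted p = 0.262 with an estimated correlation). Submucosal gland markers had a median of 0.32, with 0 of 18 members higher over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00868; adjusted p = 0.696 with an estimated correlation). LTF, the lactoferrin of gland secretions, was at 2.14 ± 0.62 here but at -0.98 ± 0.60 at day 100 and -1.84 ± 0.61 at birth, where it stood at 106 ± 30.1 CPM in CF against 378 ± 53.8 in WT (adjusted p = 1, 0.524 and 0.395, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Ionocyte markers had a median of -0.31 with 0 of 23 members lower over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00171; adjusted p = 0.225 with an estimated correlation). Further lists past camera were, higher in CF, fibroblasts and matrix, endothelium and hypoxia and, lower in CF, epithelium and oxidative phosphorylation. Their camera adjusted p ran from 1.18e-05 to 0.0283, and with an estimated correlation the adjusted p ran from 0.262 to 0.968. Liver genes, of the list added later, lay higher at day 120 (camera 0.00602, 0.967), with CF day 120 replicate 2 high.

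At birth genes induced by low oxygen were again higher in CF. EGLN3 stood at 171 ± 5.19 CPM in CF against 15.5 ± 3.2 CPM in WT (SD, n = 2 each), a log2 fold change of 3.47 ± 0.30 (SE). SLC2A3 rose by 2.92 ± 0.46, PDK1 by 1.92 ± 0.25 and CDA, a cytidine deaminase, by 3.80 ± 0.62. IGF2BP1, a fetal RNA-binding protein, was at 0 counts in WT and at 0.757 ± 0.222 CPM in CF, at least 25.0-fold higher against a floor of 3 counts over the group and at least 11.4-fold without WT day 147 replicate 1. GCLC, which makes the precursor of glutathione, was at -2.29 ± 0.38 log2, SLC2A6 at -2.98 ± 0.49, HSPA2 at -2.21 ± 0.34, NEK2, a mitotic kinase, at -2.07 ± 0.34 and FAM217A at -4.58 ± 0.49. These were among 19 called genes, 10 higher and 9 lower in CF, and their adjusted p ran from 0.000874 to 0.0492 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). SLC2A6 (-2.17, not passing) moved by over 1.5-fold to this log2 value without WT day 147 replicate 1. Of 10 named genes called here, 9 lost the call without 1 library or another, 9 of them without CF day 147 replicate 1.

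Of the hypoxia list 3 of 35 members were higher over all genes and 18 adjusted over the list alone (camera adjusted p = 1.61e-19; adjusted p = 0.000139 with an estimated correlation). Cell cycle genes had 0 of 92 members lower over all genes and 17 adjusted over the list alone (camera adjusted p = 1.13e-10; adjusted p = 0.311 with an estimated correlation). CDC20 was at -2.43 log2. Macrophage and neutrophil genes had 0 of 38 members lower over all genes and 10 adjusted over the list alone (camera adjusted p = 3.87e-09; adjusted p = 0.276 with an estimated correlation). The complement gene C1QB was at -2.32. Inflammation genes had 0 of 42 members lower over all genes and 8 adjusted over the list alone (camera adjusted p = 3.25e-05; adjusted p = 0.311 with an estimated correlation). CCL20 was at -5.17. Immediate early genes had 0 of 35 members higher over all genes and 9 adjusted over the list alone (camera adjusted p = 0.00395; adjusted p = 0.697 with an estimated correlation). These included the stress genes DNAJB1 (2.50) and HSPA1A (3.43). Basal cell genes had 0 of 28 members higher over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000494; adjusted p = 0.311 with an estimated correlation). Fibroblast markers had a median of -0.67 with 0 of 52 members lower over all genes and 1 adjusted over the list alone (camera adjusted p = 2.25e-07; adjusted p = 0.311 with an estimated correlation). The lists at birth were not tested with the CF libraries summed, so their p-values take these as separate samples. Summing leaves the mean of the pair nearly as it was, so it can lower the number of calls but hardly turn a direction. Both CF libraries of this age share an identifier, and with these alone summed into 1 sample 1 gene passed, while 19 of the 19 kept their direction, with a median ratio of the log2 fold changes of 1.000. The WT day 100 libraries alone summed left 6. Library size alone gave 8 higher and 4 lower genes, and leaving out 1 library moved this count by over 1.5 times in 19 of 20 fits, from 1 without CF day 147 replicate 1 to 56 without WT day 80 replicate 2. For birth larger counts of called genes were 425 (192 higher, 233 lower) by DESeq2, 35 (20 higher, 15 lower) by limma-voom, 32 (17 higher, 15 lower) with the stricter filter, 315 (162 higher, 153 lower) with the length slope as a covariate and 48 (21 higher, 27 lower) without the 5 libraries of low length slope. For birth smaller counts of called genes were 8 (4 higher, 4 lower) with RLE size factors, 6 (4 higher, 2 lower) with no filter, 1 with both pairs of a shared identifier summed, 0 (778 at an unadjusted p under 0.05) in the fit of the 4 samples alone and 7 (3 higher, 4 lower) without the 4 libraries holding other tissue.

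From day 65 to birth the lists of secretory and of multiciliated cells lay higher in the WT trachea by camera, and those of the cell cycle and of matrix lower. None of the 27 lists past the camera threshold passed with an estimated correlation. PIGR rose from 3.63 ± 2.49 to 1524 ± 248 CPM (SD, n = 2 each), a log2 fold change of 8.72 ± 0.76 (SE). LTF rose by 7.79 ± 0.80, BPIFB1, an antimicrobial protein of airway secretions, by 7.63 ± 0.79, and AQP5, a water channel of glands, by 7.55 ± 0.77. MSMB (11.25), GP2 (8.45), MPO (8.09), the myeloperoxidase of neutrophils, and ZG16B (7.76) were further large increases, as were FABP4 (9.64) and PLIN1 (8.69), both of fat cells, a list whose score was 4.35 and -0.15 in the WT libraries of this age. In all 1654 genes passed, 743 higher and 911 lower at birth. BPIFB1 (6.83), FABP4 (10.52), MSMB (9.72) and PLIN1 (9.70) moved by over 1.5-fold to these log2 values without WT day 147 replicate 2. FABP4 (10.23), GP2 (7.72), MPO (9.03), PIGR (9.66) and ZG16B (7.15) moved by over 1.5-fold to these log2 values without WT day 65 replicate 2. FABP4 (7.25), MPO (7.24), MSMB (11.98) and PLIN1 (3.19, not passing) moved by over 1.5-fold to these log2 values without WT day 147 replicate 1. GP2 (10.02), MPO (7.46) and ZG16B (9.01) moved by over 1.5-fold to these log2 values without WT day 65 replicate 1.

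IGF2BP1 fell from 26.1 ± 15.5 CPM to 0 counts, at least 859-fold lower against a floor of 3 counts over the group and at least 393-fold without WT day 147 replicate 1. COL24A1, a fibrillar collagen of growing tissue, fell to 0.926 ± 0.560 CPM from 43.3 ± 15.2 (-5.54 ± 0.49 log2). PRSS35 (-5.41), PRND (-6.82), SLIT1 (-6.09), SCEL (-5.70), VAT1L (-5.13) and FBN3 (-5.05), a fetal fibrillin, fell too. So did ALAS2 (-5.37), of red cells, and CD8B (-5.19), of T cells, the latter a gene of the thymus, whose score was 4.28 in WT day 65 replicate 2 and -0.49 in its partner. ALAS2 (-6.57), CD8B (-4.60) and COL24A1 (-6.35) moved by over 1.5-fold to these log2 values without WT day 147 replicate 1. ALAS2 (-4.70, not passing), CD8B (-6.20), SCEL (-6.63) and SLIT1 (-6.77, not passing) moved by over 1.5-fold to these log2 values without WT day 147 replicate 2. CD8B (-6.03), SCEL (-4.94) and SLIT1 (-6.95, not passing) moved by over 1.5-fold to these log2 values without WT day 65 replicate 1. CD8B (-2.94, not passing) and SLIT1 (-3.65, not passing) moved by over 1.5-fold to these log2 values without WT day 65 replicate 2. Of 31 named genes called here, 10 lost the call without 1 library or another, 8 of them without WT day 65 replicate 1. The adjusted p of the named genes ran from 0.000329 to 0.0383 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

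Of the cell cycle list 60 of 92 members were lower over all genes and 74 adjusted over the list alone (camera adjusted p = 7.57e-31; adjusted p = 0.0576 with an estimated correlation). NUSAP1, of the mitotic spindle, was at -1.82 log2. Of the fibroblast and matrix list 15 of 52 members were lower over all genes and 22 adjusted over the list alone (camera adjusted p = 1.51e-07; adjusted p = 0.197 with an estimated correlation). FBN2 was at -3.41. Of the Wnt list 12 of 70 members were lower over all genes and 20 adjusted over the list alone (camera adjusted p = 1.94e-07; adjusted p = 0.0576 with an estimated correlation). FZD2 was at -2.68. Of the secretory and goblet list 13 of 38 members were higher over all genes and 15 adjusted over the list alone (camera adjusted p = 1.15e-05; adjusted p = 0.0576 with an estimated correlation). Of the submucosal gland list 5 of 18 members were higher over all genes and 7 adjusted over the list alone (camera adjusted p = 0.000669; adjusted p = 0.187 with an estimated correlation). TCN1, a vitamin B12 binder, was at 5.66 and LPO at 7.27.

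Multiciliated cell genes had 16 of 120 members higher over all genes and 93 adjusted over the list alone (camera adjusted p = 2.00e-21; adjusted p = 0.302 with an estimated correlation). CDHR3 was at 2.99 log2. Interferon response genes had 12 of 44 members higher over all genes and 16 adjusted over the list alone (camera adjusted p = 1.51e-07; adjusted p = 0.172 with an estimated correlation). MX1 was at 2.73. Macrophage and neutrophil genes had 11 of 38 members higher over all genes and 14 adjusted over the list alone (camera adjusted p = 1.98e-06; adjusted p = 0.172 with an estimated correlation). S100A8 was at 6.74. Antigen presentation genes had 4 of 12 members higher over all genes and 6 adjusted over the list alone (camera adjusted p = 8.78e-05; adjusted p = 0.241 with an estimated correlation). B2M was at 1.36. Glucocorticoid response genes had 6 of 37 members higher over all genes and 10 adjusted over the list alone (camera adjusted p = 0.000126; adjusted p = 0.172 with an estimated correlation). KLF9 was at 3.49. With library size alone the calls were 471 higher and 1298 lower, and the median of all genes was -0.36 log2 against -0.02 with TMM. S100A8 (6.11) moved by over 1.5-fold to this log2 value without WT day 147 replicate 2. For WT development larger counts of called genes were 4078 (2150 higher, 1928 lower) by DESeq2 and 3270 (1318 higher, 1952 lower) with the length slope as a covariate. For WT development smaller counts of called genes were 982 (439 higher, 543 lower) with both pairs of a shared identifier summed, 0 (3072 at an unadjusted p under 0.05) in the fit of the 4 samples alone and 986 (437 higher, 549 lower) without the 4 libraries holding other tissue. Leaving out 1 library gave 408 without WT day 65 replicate 1, 590 without WT day 65 replicate 2, 2665 without WT day 80 replicate 1, 2695 without WT day 80 replicate 2, 3292 without WT day 147 replicate 1 and 460 without WT day 147 replicate 2.

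**Figure D4:**
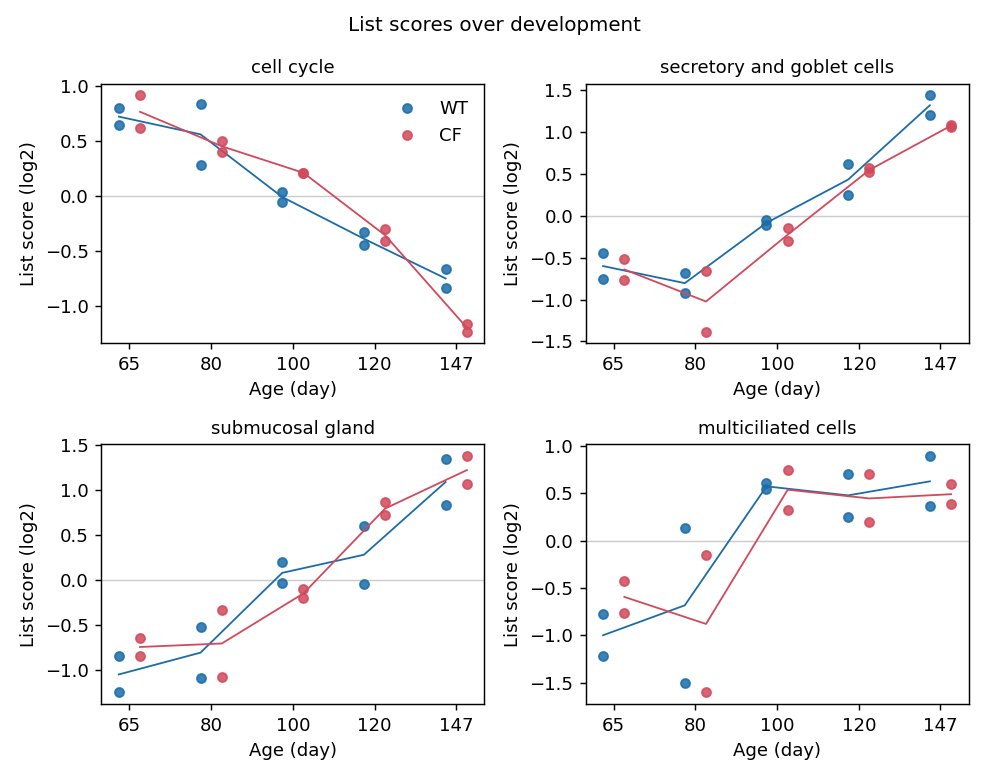
Scores of the cell cycle, secretory, submucosal gland and multiciliated lists (y axis, mean log2 deviation from the average library) against age in days (x axis), blue points for WT and red for CF libraries, lines through group means. Cell cycle scores lie at 0.64 and 0.80 in WT at day 65 and at -0.67 and -0.84 at birth.

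In the CF trachea the secretory list lay higher and the cell cycle list lower at birth than at day 65, also with an estimated correlation. PIGR rose from 0.785 ± 0.335 to 1193 ± 185 CPM (SD, n = 2 each; 10.56 ± 0.82 log2), GP2 by 9.08 ± 1.40, ZG16B by 7.09 ± 1.21 and MSMB by 6.86 ± 1.25. CLCA1 (7.37) and ITLN (7.56), products of goblet cells, HSPA6 (6.63), a heat shock gene, SLC5A8 (6.56), VNN2 (6.81) and FABP4 (7.66) were the other largest increases. VAT1L (-6.02), WFIKKN2 (-5.97), PRND (-5.82), COL24A1 (-5.58), SPP1 (-5.55), FBN3 (-5.42) and ALAS2 (-5.71) fell, as did the plasma protein genes AHSG (-8.51), HPX (-5.44) and FGB (-5.34), which were high in CF day 65 replicate 2 (AHSG at 5346 against 5.15 CPM in its partner). AHSG (-9.50), ALAS2 (-6.64), CLCA1 (8.0, not passing), FGB (-6.32), GP2 (10), HPX (-6.42), ITLN (8.59, not passing), MSMB (6.13, not passing) and SLC5A8 (7.42) moved by over 1.5-fold to these log2 values without CF day 65 replicate 1. AHSG (0.51, not passing), ALAS2 (-2.32, not passing), FGB (-0.09, not passing), HPX (-0.11, not passing), ITLN (6.96, not passing), MSMB (8.27) and SPP1 (-4.92) moved by over 1.5-fold to these log2 values without CF day 65 replicate 2. FABP4 (8.54), GP2 (8.37) and WFIKKN2 (-6.56) moved by over 1.5-fold to these log2 values without CF day 147 replicate 1. FABP4 (5.02, not passing) and PRND (-6.76) moved by over 1.5-fold to these log2 values without CF day 147 replicate 2. Of 27 named genes called here, 14 lost the call without 1 library or another, 12 of them without CF day 65 replicate 2. In all 1104 genes passed, 358 higher and 746 lower at birth, the named ones with adjusted p from 0.000108 to 0.0442 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

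Of the cell cycle list 72 of 92 members were lower over all genes and 86 adjusted over the list alone (camera adjusted p = 4.54e-63; adjusted p = 0.0131 with an estimated correlation). CENPE, a motor of the kinetochore, was at -3.01 log2. Of the secretory and goblet list 7 of 38 members were higher over all genes and 15 adjusted over the list alone (camera adjusted p = 3.99e-07; adjusted p = 0.0298 with an estimated correlation). GALNT6, which starts mucin sugar chains, was at 3.13. Of the immediate early list 12 of 35 members were higher over all genes and 19 adjusted over the list alone (camera adjusted p = 1.76e-12; adjusted p = 0.0435 with an estimated correlation). NR4A2 was at 3.28. Of the interferon list 7 of 44 members were higher over all genes and 16 adjusted over the list alone (camera adjusted p = 1.03e-12; adjusted p = 0.0435 with an estimated correlation). Among hypoxia genes 3 of 35 members were higher over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000501; adjusted p = 0.0331 with an estimated correlation). ADM was at 2.95. Of the ionocyte list 3 of 23 members were higher over all genes and 8 adjusted over the list alone (camera adjusted p = 0.000730; adjusted p = 0.0435 with an estimated correlation). ATP6V1B1, a proton pump subunit, was at 3.11. Nerve and Schwann cell genes had 5 of 38 members lower over all genes and 13 adjusted over the list alone (camera adjusted p = 3.12e-07; adjusted p = 0.0131 with an estimated correlation). NEFL, a neurofilament, was at -4.70. Imprinted genes had 5 of 30 members lower over all genes and 8 adjusted over the list alone (camera adjusted p = 2.86e-05; adjusted p = 0.0331 with an estimated correlation). MEST was at -3.40. Of 23 lists past the camera threshold, 10 passed with an estimated correlation. With library size alone the calls were 256 higher and 1033 lower, and the median of all genes was -0.23 log2 against -0.01 with TMM. For CF development larger counts of called genes were 2387 (924 higher, 1463 lower) by DESeq2, 3284 (1608 higher, 1676 lower) in the fit of the 4 samples alone, 1732 (653 higher, 1079 lower) with a linear trend on day, 3290 (1274 higher, 2016 lower) with the length slope as a covariate and 2542 (961 higher, 1581 lower) without the 5 libraries of low length slope. For CF development smaller counts of called genes were 134 (55 higher, 79 lower) with both pairs of a shared identifier summed, 532 (182 higher, 350 lower) without the 4 libraries holding other tissue and 314 (120 higher, 194 lower) with the CF day 147 pair summed. Leaving out 1 library gave 580 without CF day 65 replicate 1, 363 without CF day 65 replicate 2, 349 without CF day 147 replicate 1 and 322 without CF day 147 replicate 2.

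Many genes changed in the same direction in both genotypes over development. Across 20097 genes the log2 fold changes of WT and CF had a Pearson r of 0.50 and a Spearman rho of 0.57, and 0.72 and 0.68 over the 14206 genes with a mean log2 CPM of at least 1. These are correlations across genes, which are not independent replicates. The same 233 genes were called higher in both, where lists drawn independently would share 13.2, and 471 were called lower in both against 33.8. PIGR, GP2 and ZG16B are among the former and COL24A1, VAT1L and PRND among the latter. Of the genes called in both, 0 went opposite ways.

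The difference between the developments was also tested itself. ADGRE5, the leukocyte adhesion receptor CD97, had a log2 change from day 65 to birth that was -1.89 ± 0.23 apart in CF and WT, lower in CF (adjusted p = 0.0424, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It was the 1 gene called, with 962 at an unadjusted p under 0.05, 111 called by DESeq2 and 1 by limma-voom, and leaving out 1 library moved this count by over 1.5 times in 18 of 20 fits, from 0 without WT day 65 replicate 1 to 31 without CF day 65 replicate 1. For this difference a larger count of called genes was 2 (0 higher, 2 lower) with the length slope as a covariate. For this difference smaller counts of called genes were 0 (880 at an unadjusted p under 0.05) with library size alone, 0 (984 unadjusted) with no filter, 0 (472 unadjusted) with both pairs of a shared identifier summed, 0 (640 unadjusted) without the 4 libraries holding other tissue, 0 (1395 unadjusted) without the 5 libraries of low length slope, 0 (874 unadjusted) with the WT day 100 pair summed and 0 (546 unadjusted) with the CF day 147 pair summed. Of the hypoxia list 0 of 35 members were higher over all genes and 5 adjusted over the list alone (camera adjusted p = 7.97e-05; adjusted p = 0.0630 with an estimated correlation). EGLN3 was at 2.20 log2. Of the inflammation list 0 of 42 members were lower over all genes and 1 adjusted over the list alone (camera adjusted p = 4.80e-05; adjusted p = 0.397 with an estimated correlation). Of macrophage and neutrophil genes 0 of 38 members were lower over all genes and 0 adjusted over the list alone (camera adjusted p = 2.04e-07; adjusted p = 0.293 with an estimated correlation). MPO was at -5.06. In all 16 of 40 lists passed camera for this difference, 7 higher and 9 lower in CF, and 0 passed with an estimated correlation. Fewer passed camera without the 4 libraries holding other tissue.

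A test of whether the genotype difference is the same at every age called 14 genes, 820 by DESeq2 and 18 by limma-voom. EGLN3 led them, with log2 differences of 1.27 at day 65, 0.88 at day 80, -1.21 at day 100, 0.29 at day 120 and 3.47 at day 147 (adjusted p = 0.0189, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). FAM217A, ANGPTL1, ADGRE5, FNDC1 and MDGA1 followed by p, and 2 of the 14, COL14A1 and COL6A1, are members of the fibroblast and matrix list. Of the 14 genes 11 had their largest difference at day 100, all higher in CF there. For these genes too, leaving out 1 library moved this count by over 1.5 times in 20 of 20 fits, from 0 without WT day 100 replicate 1 to 216 without WT day 80 replicate 1. For this test larger counts of called genes were 207 with the length slope as a covariate and 472 without the 5 libraries of low length slope. For this test smaller counts of called genes were 2 with RLE size factors, 9 with library size alone, 4 with the stricter filter, 0 (658 at an unadjusted p under 0.05) with both pairs of a shared identifier summed, 0 (1217 unadjusted) without the 4 libraries holding other tissue, 0 (991 unadjusted) with the WT day 100 pair summed and 0 (1098 unadjusted) with the CF day 147 pair summed.

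Markers of the main cell types did not pass over the mean of the ages, with adjusted p from 0.272 to 1.000 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). FOXJ1, of ciliated cells, was at -0.37 ± 0.32 log2, TP63 and KRT5, of basal cells, at 0.31 ± 0.22 and 0.03 ± 0.28, SCGB1A1, of club cells, at 0.14 ± 0.67, with 2 counts in WT at day 80, and EPCAM at -0.40 ± 0.18. The mucins MUC5AC and MUC5B, named through the gene table for identifiers without a symbol, were at -0.35 ± 0.78 and 0.26 ± 0.71, and POU2F3, of tuft cells, at 0.12 ± 0.53. COL2A1, of cartilage, was at 0.11 ± 0.37, MYH11, of smooth muscle, at -0.18 ± 0.43, MKI67, of dividing cells, at -0.07 ± 0.43, PTPRC, of leukocytes, at -1.14 ± 0.56, TG at -2.88 ± 1.00 and ACTA1 at 0.20 ± 1.05. PTPRC was high in WT day 65 replicate 2 and WT day 80 replicate 2 (62.7 and 64.9 CPM), TG in WT day 80 replicate 2 and ACTA1 in CF day 80 replicate 1. Without the 4 libraries holding other tissue PTPRC was at 0.27 log2, TG at 0.15 and ACTA1 at -0.51. IGF2, a fetal growth factor, was at 1.08 ± 0.42 in the mean and at 4.65 ± 1.09 at day 100 (adjusted p = 0.348 and 0.0578, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). From day 65 to birth SCGB1A1 rose in WT by 7.84 ± 2.00 and stood at 6.39 ± 1.92 in CF (adjusted p = 0.0306 and 0.0777, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), the difference between these not passing (adjusted p = 0.937, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). SCGB1A1 (7.18, not passing) moved by over 1.5-fold to this log2 value without WT day 65 replicate 1. SCGB1A1 (8.56) moved by over 1.5-fold to this log2 value without WT day 147 replicate 1. SCGB1A1 (6.32, not passing) moved by over 1.5-fold to this log2 value without WT day 147 replicate 2. As a ratio of counts it was 445 (123 to 3675) without WT day 65 replicate 2, where 2 counts remained at day 65, and did not pass there. Mucin genes share repeats with close relatives, so their counts are uncertain, as are those of genes with an antisense partner, since the strand setting of the counting is not given in the sources used here.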

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

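The tests of stroma and of a lasting difference at day 100, those of thyroid and fetal liver and the splits that keep samples of an identifier together were chosen only after those results were seen, and the fits with the length slope and without 4 libraries after the data were seen. Tests of a difference between groups picked out the following genes. ADGRE5 had a change from day 65 to birth that differed between CF and WT by -1.89 log2. The genotype difference varied with age in 14 genes, with an adjusted p of 0.0189 for EGLN3; of 0.0206 for FAM217A; of 0.0423 for ANGPTL1, ADGRE5, FNDC1, MDGA1, COL14A1, AKAP12, COL6A1, BMP1, ANGPTL2 and S1PR2; of 0.0482 for ADAMTS2 and LTBP4 (edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment).

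For the 154 genes called over the mean of the ages, 3 of 100 splits that keep 2 and 2 samples in each age called as many, the real one included. Of 100 splits that also keep the WT day 100 and the CF day 147 samples together, 2 did. A count of this size was thus uncommon in relabelled samples, but chance is not excluded, as other splits called more. WT day 65 replicate 2 and CF day 100 replicate 2, which share an identifier, were not kept together. The highest other splits called 2583 and 3152, which points to a structure of the samples that is not genotype. The median ratio of the called genes' log2 fold changes was 0.993 with the length slope as a covariate and 0.989 without the 4 libraries holding other tissue. The fold of the typical called gene thus did not rest on either. Genes whose replicates agree are the ones called, so this says little of genes that other tissue moves. SCNN1B went from -2.13 to -1.25 log2 without WT day 80 replicate 2. Most calls were lost without the 4 libraries. Fewer samples alone need not account for this, as most calls stayed without the 5 libraries of low length slope. The calls, unlike the typical fold, thus depended on the 4 libraries. Of the called genes 0.649% lay within 20 Mb of CFTR, against 0.990% of all tested genes. This argues against most calls coming from linked alleles that act on genes near CFTR. It does not bear on linked alleles that act on distant genes, or on differences elsewhere in the genome. With the WT day 100 and the CF day 147 pairs summed 154 of the 154 kept their direction, with a median ratio of the log2 fold changes of 0.993, and few stayed called. Summing leaves the group means nearly as they were, so the kept direction does not bear on shared animals, which stay open for the calls. Genotype, litter and any difference in preparation between the WT and CF samples, whose counts come in separate tables, stay open, untested.

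For the genes higher in CF at day 100, the departure lay in WT: their median log2 level there was -2.15 against the mean of WT days 80 and 120, and -0.14 in CF by the same measure. A low stromal content of the tissue taken for the WT day 100 libraries may account for them. Over all genes called at day 100, the median ratio of the mean difference at the other ages to that at day 100 was 0.0147. Picking genes for a large difference at day 100 lowers this ratio. So low a value still argues, for these genes, against a genotype difference of similar size at every age. Both WT libraries carry the same identifier, and whether the low stroma belongs to a single animal, to its dissection or to WT sheep of this age cannot be seen from these samples.

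Markers of other tissues stood out in single libraries. In WT day 80 replicate 2, 14 thyroid markers other than TG had a median log2 ratio of 4.07 to the other WT day 80 library, so thyroid tissue may have been taken with the trachea. In CF day 65 replicate 2, 19 erythroid markers had a median log2 ratio of 5.69 to the other CF day 65 library beside the plasma protein genes, and fetal liver, which makes both, is a candidate source. No biological explanation was tested, as no group of the design holds these libraries alone.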

How the results depend on the processing

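The fits with the length slope as a covariate, without 4 libraries and without the 5 of lowest length slope, and those with the WT day 100 or the CF day 147 samples alone summed, were chosen only after the data were seen. Called genes in the edgeR test were 154 (the mean of the ages), 2 (day 65), 0 (day 80), 294 (day 100), 0 (day 120), 19 (day 147), 1654 (WT development), 1104 (CF development), 1 (their difference) and 14 (variation with age). Counts over 1.5 times off follow, and the cause was not tested except where samples or genes were left out. DESeq2 gave 827 (the mean of the ages), 150 (day 65), 693 (day 80), 1210 (day 100), 17 (day 120), 425 (day 147), 4078 (WT development), 2387 (CF development), 111 (their difference) and 820 (variation with age). Limma-voom gave 0 (day 65) and 35 (day 147). RLE size factors gave 8 (day 147) and 2 (variation with age). Library size alone gave 1 (day 65), 12 (day 147), 0 (their difference) and 9 (variation with age). No filter gave 6 (day 147) and 0 (their difference). Stricter filter gave 32 (day 147) and 4 (variation with age). Summing samples with a shared identifier gave 2 (the mean of the ages), 0 (day 65), 0 (day 100), 1 (day 147), 982 (WT development), 134 (CF development), 0 (their difference) and 0 (variation with age). Mean without day 80 gave 99 (the mean of the ages). Mean without day 100 gave 51 (the mean of the ages). Mean without day 147 gave 90 (the mean of the ages). 1 surrogate variable gave 888 (the mean of the ages). Library length slope as a covariate gave 790 (the mean of the ages), 6 (day 65), 67 (day 80), 750 (day 100), 315 (day 147), 3270 (WT development), 3290 (CF development), 2 (their difference) and 207 (variation with age). Without the 4 libraries with neighbouring tissue gave 49 (the mean of the ages), 0 (day 65), 7 (day 147), 986 (WT development), 532 (CF development), 0 (their difference) and 0 (variation with age). Without the 5 libraries of low length slope gave 387 (the mean of the ages), 1772 (day 80), 550 (day 100), 1 (day 120), 48 (day 147), 2542 (CF development), 0 (their difference) and 472 (variation with age). WT day 100 samples summed gave 49 (the mean of the ages), 0 (day 100), 6 (day 147), 0 (their difference) and 0 (variation with age). CF day 147 samples summed gave 52 (the mean of the ages), 0 (day 65), 1 (day 147), 314 (CF development), 0 (their difference) and 0 (variation with age). Fits of 4 samples gave 5759 (day 100), 0 (day 147), 0 (WT development) and 3284 (CF development). A linear trend on day gave 1732 (CF development).

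With the replicate number as a block the counts were 103 (the mean of the ages), 1 (day 65), 0 (day 80), 238 (day 100), 0 (day 120), 3 (day 147), 1370 (WT development), 905 (CF development), 0 (their difference) and 1 (variation with age). The numbers do not pair the samples, since deviations of samples with the same number had correlations from -0.59 to 0.73 over 45 pairs of groups, 12 of them over 0.1.

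Leaving out each library in turn, with a lone sample assumed to vary like the other groups, gave 51 to 319 (the mean of the ages), 0 to 46 (day 65), 0 to 352 (day 80), 0 to 482 (day 100), 0 to 0 (day 120), 1 to 56 (day 147), 408 to 3292 (WT development), 322 to 1443 (CF development), 0 to 31 (their difference) and 0 to 216 (variation with age). Lists past the camera threshold over all comparisons numbered 153, 15 with an estimated correlation and 53 with fry. The correlation of the developments was 0.72 over genes with a mean log2 CPM of at least 1.

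Of 171 values of named genes 131 passed, 10 of them in every fit. The direction of AHSG in CF development, -8.51 log2, turned without the 4 libraries, at 0.51, and ran from -9.50 to 0.51 with 1 library left out, the highest without CF day 65 replicate 2. Depth limits genes near the floor, such as IL1RL2 with 2 counts in WT at day 100 and a counting interval of the ratio from 127 to 3812.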

Other observations

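The values here were picked after the data were examined, and none was tested further. Fat cell markers differed between replicates at several ages. Their score was 0.25 and -1.63 in CF at day 80, 3.58 and -0.07 in WT and 2.81 and 1.62 in CF at day 120, 4.35 and -0.15 in WT at birth, and 0.58 and 3.17 in CF at birth. Immediate early genes had scores of 1.72 and 1.42 in CF at birth and of 0.18 and 1.37 in WT.

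The share of even values among low counts was 78.3% in CF day 120 replicate 1 to 85.3% in WT day 100 replicate 1 over the 5 libraries of lowest length slope, and 70.7% in WT day 147 replicate 1, the lowest of all.

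Genes of the mitochondrial chromosome took from 1.01% of the counts in WT day 80 replicate 1 to 9.90% in CF day 147 replicate 2. The leading principal component held 29.3% of the variance between libraries, and its ends were WT day 147 replicate 2 and WT day 65 replicate 2, with length slopes of -0.342 and 0.232. SCGB3A2, a secretoglobin of the airway, took 6.48% of the counts of WT day 147 replicate 2, the largest share of any gene there.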
